A study of Homo sapiens with 6 samples.

How the data were processed

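Total RNA was sequenced from HCT116 cells, a human colorectal carcinoma line, in a derivative labelled TP53 -/-. Per the labels' protocols, the RNA was extracted with Trizol, libraries were made with a stranded Illumina total RNA kit, and cells received either DMSO or the RNA polymerase I inhibitor BMH-21 at 1 µM for 6 h. The labels list 3 control samples, titled as 0 h, and 3 BMH-21 samples, titled as 6 h. How long the control cells were held in DMSO is not given in the sources used here, so an effect of time in culture cannot be separated from that of BMH-21. The series text states 3 biological replicates.

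The deposited values are FPKM (fragments scaled by transcript length and library size), 1 row per gene symbol for 25548 symbols. TopHat2, Cuffdiff 2.0 and the genome build GRCh37 are named in the submitters' processing notes, without their roles. The gene annotation, the handling of reads with several matches, any masking of abundant RNAs, the use of strand and the scaling between libraries are not given in the sources used here. Reads of a gene and of an antisense or overlapping partner therefore cannot be told apart. The reference in hand was on another build, so no coordinates are given.

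The table has 3 columns per group, which its header numbers as replicates, but their values are not those of 3 libraries. The column numbered 1 lay at the midpoint of the columns numbered 2 and 3, within 0.1%, in 15367 of the 15374 control genes with a column 2 value above 0 (99.95%), and in 15596 of the 15604 such BMH-21 genes (99.95%). The column numbered 2 was lowest and the column numbered 3 highest, ties included, in 99.96% of control genes and 99.95% of BMH-21 genes. Column 2 was exactly 0 in 4584 control genes and 4719 BMH-21 genes with a column 1 value above 0. The 3 columns were accordingly read as 1 FPKM estimate per group with a lower bound, cut at 0, and an upper bound. The confidence level of the bounds and whether the estimates pool 3 libraries are not stated. Genes whose lower bound was cut at 0 were left out of the percentiles that follow. Among the other genes of at least 1 FPKM, the half-width was 17.7% of the control estimate at the median. In control it was 16.7% at the 1st percentile and 38.5% at the 95th percentile. In BMH-21 it was 17.8%, 16.7% and 38.5%.

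A test between replicates with limma had been planned for 3 values per group, with values and no test for the case of 1 value per group. The second case applied. The calls by interval and the random lists described below were not part of that plan and took the place of the planned tests. No p-value is given, and differences have no replicate check. Genes with a mean FPKM of at least 1 over both estimates were kept (12193). A gene was called higher or lower when the deposited intervals of the 2 groups did not overlap. Log2 ratios are BMH-21 over control on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes, and "±" gives the half-widths of both intervals combined as the root of their summed squares on that scale. The calls did not use the "±", which is narrower than the overlap rule, so a gene with overlapping intervals can have a ratio larger than its "±". FPKM carry no count, so the sequencing depth is unknown. Low values showed no steps from which whole reads could be recovered.

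Before the data were examined, 32 gene lists, the rule for named genes and the processing alternatives were fixed. Each of the 29 lists with at least 5 members passing the filter was described by the median log2 ratio of its members, set against 10000 random lists of the same size matched on mean FPKM in 20 bins. A list was called outside when its median left the central 95% (2.5th to 97.5th percentile) of the random medians. The percentile describes these 2 estimates and is not a test of the conditions. The named genes were 12 fixed symbols, the 10 highest and 10 lowest log2 ratios among genes with a mean of at least 5 FPKM, and up to 4 members of each list with the largest changes, or 2 where no member was called. In the rule, intervals apart took the place of an adjusted p and of separate replicates. Symbols of short RNAs (such as SNORD, SNORA, RNU and numbered MIR genes) were left out of the ranking by the rule.

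The calls were checked on simulated estimates for the comparison of control with BMH-21 over 11893 genes, with the deposited bounds taken as 2 SD. The noise was drawn for each gene independently from its control bounds, so the simulation holds no spread between cultures. Intervals were apart in the true direction for 65.7% of genes simulated with a 1.5-fold change, 89.6% at 2-fold and 98.5% at 4-fold, and for 0.53% of unchanged genes. Of 100 simulated unchanged lists of 40 genes, 6 fell outside the random range. Their genes were picked at random and varied independently, so this number does not apply to lists whose genes vary together. Other pseudocounts, filters and scalings were tried, as were wider intervals and the removal of a trend with transcript GC content and length. GC content and length came from 1 GENCODE 29 transcript per symbol (the longest protein-coding one, otherwise the longest). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.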

Results

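Gene expression was compared between control (DMSO) and BMH-21-treated HCT116 colorectal carcinoma cells labelled TP53 -/-, to ask how an RNA polymerase I inhibitor changes the transcriptome of cells labelled in this way. BMH-21 is a small DNA-intercalating molecule that blocks RNA polymerase I, the enzyme that transcribes the ribosomal RNA genes. The labels list 3 control samples and 3 samples treated with 1 µM BMH-21 for 6 h. The deposited table held 1 FPKM estimate with a lower and an upper bound for each group, so every value below is 1 estimate per group with its deposited interval, without a replicate check. The estimates summed to 723462 FPKM in control and 714603 FPKM in BMH-21. Precursor and mature ribosomal RNA made by RNA polymerase I could not be followed. No row for the precursor was found. Of the 25 rows for rRNA, 5S, 7SK, 7SL, RMRP and RPPH1 genes, 24 were listed at 0 in both groups. The other row, the 5S gene RN5S9, stood at 66.0 FPKM in control and 76.4 FPKM in BMH-21.

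TP53, the gene that the labels give as knocked out, was listed at 14.5 FPKM in control (interval 10.99 to 18.1) and 19.99 FPKM in BMH-21 (15.3 to 24.7), and the intervals overlapped. A gene-level value does not show which exons the reads came from, and no TP53 wild-type sample is among the labels, so these values do not check the knockout. CDKN1A, which encodes the cell cycle inhibitor p21, was higher after BMH-21, at 111.0 against 59.2 FPKM (log2 ratio 0.90 ± 0.36). MDM4, a partner and inhibitor of p53, was lower, at 5.65 against 11.03 FPKM (-0.85 ± 0.32), whereas MDM2, the p53 ubiquitin ligase, differed by less than its intervals (0.10 ± 0.39). MYC, a transcription factor that drives growth and ribosome production, was lower, at 106 against 241 FPKM (-1.17 ± 0.39). RPL22 and its paralog RPL22L1 had overlapping intervals, with log2 ratios of -0.03 ± 0.40 and -0.33 ± 0.38.

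**Figure D1:**
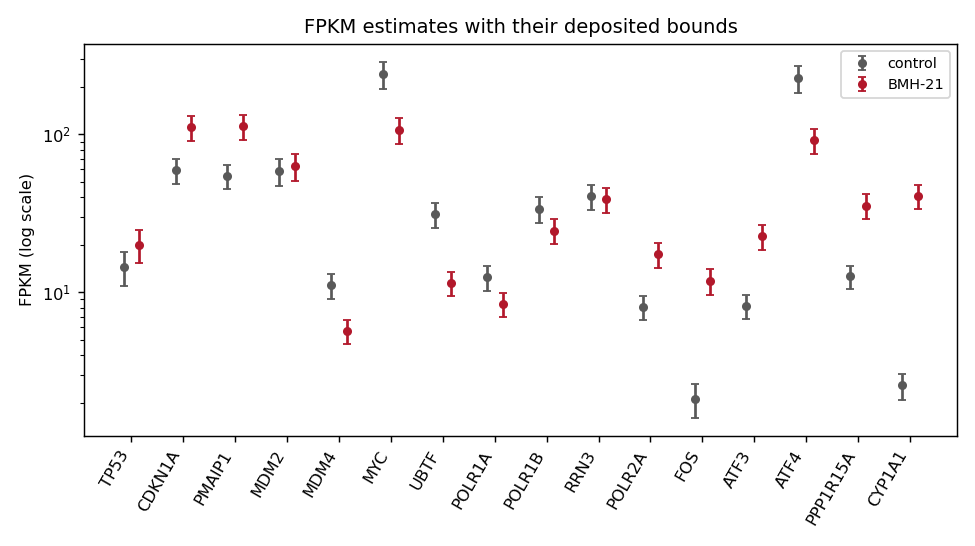
FPKM (log scale) of 16 genes in control (grey) and BMH-21 (red); points are the deposited estimates and bars the deposited lower and upper bounds, 1 estimate per group. UBTF, MYC, MDM4 and ATF4 lie lower and CYP1A1, FOS, ATF3 and CDKN1A higher in BMH-21 with bars apart, while the bars of TP53, MDM2, POLR1B and RRN3 overlap.

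Across the transcriptome, 822 of 12193 genes were higher and 1136 were lower in BMH-21 with intervals apart, and 10235 overlapped. The number apart depended on how the bounds were read. It was 780 with intervals 1.5 times as wide, and 3336 with half-widths combined as the root of their summed squares. In simulated data 0.53% of unchanged genes had intervals apart, with noise drawn from the bounds themselves, taken as 2 SD. That share holds no spread between cultures, so it is not a rate of false calls for these genes. The median log2 ratio of all genes was 0.01, and the 5th and 95th percentiles were -0.64 and 0.55. At least 2-fold changes on the log2(FPKM + 1) scale were found for 115 of the higher and 177 of the lower genes, and for 72 and 143 without short RNA genes. Short RNA symbols made up 49 of the 822 higher and 46 of the 1136 lower genes. Of the 299 short RNA genes 58 were listed at 0 in 1 group only, against 1 of 11894 other genes. The calls also followed the GC content of the transcript. The lower genes had a median GC content of 56.3% and the higher genes 44.5%, against 48.4% for genes with overlapping intervals.

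CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, had the highest log2 ratio among called genes with a mean of at least 5 FPKM, short RNA symbols left out. It stood at 2.57 FPKM in control (2.09 to 3.05) and 40.7 FPKM in BMH-21 (33.4 to 48.0), with a log2 ratio of 3.55 ± 0.32. The AP-1 subunit FOS followed among named protein-coding genes (2.05 ± 0.34), then TRIML2 (1.85 ± 0.32), the chemokine IL8 (1.70 ± 0.31), the TRAIL decoy receptor TNFRSF10D (1.70 ± 0.35), the receptor GPR15 (1.57 ± 0.35) and the small GTPase GEM (1.51 ± 0.32). LOC100287415 (2.13 ± 0.84), LOC730755 (1.69 ± 0.34) and the read-through locus TMED7-TICAM2 (1.68 ± 1.13) completed the 10 highest. The order below CYP1A1 depended on the pseudocount. With one of 5, TNFRSF10D (1.48) lay above TRIML2 (1.33), FOS (1.25) and IL8 (1.18). TMED7-TICAM2 shares its exons with its 2 member genes, so its value depends on how reads were assigned.

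Among protein-coding genes with a mean of at least 5 FPKM, TACSTD2, the surface glycoprotein Trop-2, had the lowest ratio, at 3.14 against 19.7 FPKM (-2.32 ± 0.32). TIGD5 (-2.28 ± 0.32) and SLC19A1, the reduced folate carrier, at 7.42 against 37.5 FPKM (-2.19 ± 0.33), followed. The order changed with a pseudocount of 5, with SLC19A1 at -1.78, TACSTD2 at -1.60 and TIGD5 at -1.54. GNB1L (-1.81 ± 0.85), the linker histone gene HIST1H1E (-1.79 ± 0.40), LOC645638 (-1.78 ± 0.39) and MAT2A, which makes S-adenosylmethionine (-1.74 ± 0.42), were also among the 10 lowest. The other members were short non-coding genes not covered by the symbol rule. MIRLET7E was listed at 85.0 FPKM in control and at 0 in BMH-21, and the near-identical SNAR-G2 and SNAR-G1 had ratios of -4.02 ± 0.96 and -2.84 ± 0.94.

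**Figure D2:**
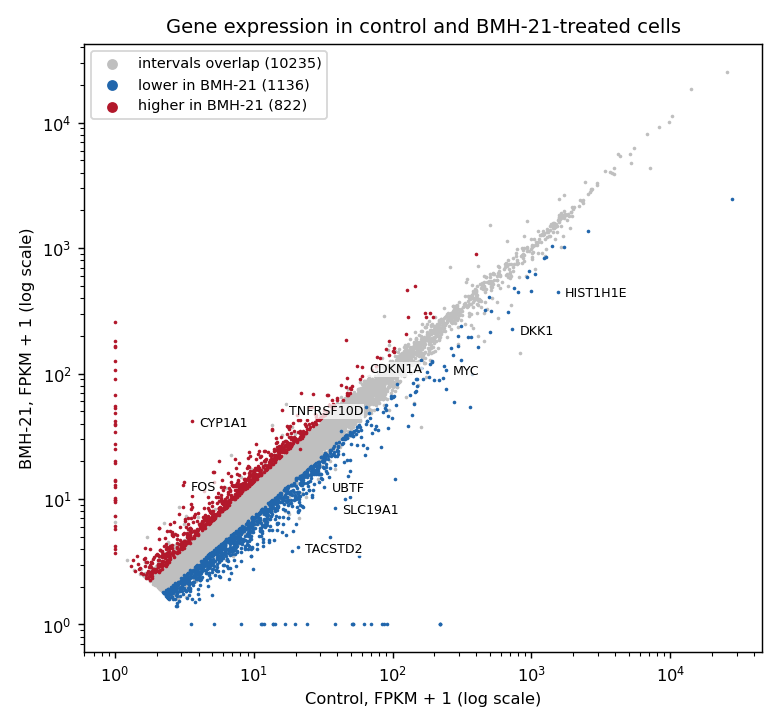
Each point is 1 of 12193 genes, with FPKM + 1 in control on the horizontal axis and in BMH-21 on the vertical axis, both on log scales and 1 estimate per group. Red points (822) are higher and blue points (1136) lower with intervals apart, and grey points (10235) overlap; points on the lines at FPKM + 1 of 1 are genes listed at 0 in that group.

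Of the 29 gene lists, 7 had medians outside the range of matched random lists. The number expected is 1.45 if all genes vary independently. Genes of a list can vary together and some lists share members, so the 7 cannot be judged against that number. None of the 47 large-subunit and 32 small-subunit ribosomal protein genes had intervals apart, with median log2 ratios of 0.02 and 0.10 (-0.03 and 0.04 when the groups were scaled on these genes). Random lists matched to the large-subunit genes held a mean of 3.68 genes apart (central 95% from 1 to 7), and those matched to the small-subunit genes 2.54 (0 to 6). The members farthest from 0 relative to their intervals were RPL39 (0.19 ± 0.41), RPL23A (0.16 ± 0.43), FAU (0.25 ± 0.47) and RPS20 (0.19 ± 0.41). Ribosome assembly factors, the nucleolar proteins that process rRNA and build the subunits, had a median of -0.12, below all 10000 matched random lists (central 95% from -0.02 to 0.10). Of the 94 factors 68 had a ratio below 0, but only 8 were lower with intervals apart and 2 were higher. These 10 compare with a mean of 9.49 apart in random lists. The lower ones included IMP3 (-0.92 ± 0.35), MYBBP1A (-0.88 ± 0.36) and RRP7A (-0.70 ± 0.34), and RRP8, an rRNA methyltransferase, was higher (0.74 ± 0.32). The snoRNA host genes had the lowest median of the 29 lists, -0.27 (random range -0.11 to 0.18), with 13 of 14 ratios below 0. SNHG7 alone had intervals apart, at 45.8 against 136.6 FPKM (-1.55 ± 0.53). Of the 76 mitochondrial ribosomal protein genes 3 were lower, MRPL34 (-1.07 ± 0.34), MRPL12 (-0.90 ± 0.36) and MRPS26 (-0.81 ± 0.35), and none was higher. Random lists matched to these genes held a mean of 6.70 apart (central 95% from 2 to 12).

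Among the 16 genes of the RNA polymerase I machinery, UBTF, the architectural factor of ribosomal RNA genes, was lower at 11.5 against 31.1 FPKM (-1.37 ± 0.35). The largest subunit gene POLR1A was lower as well (-0.51 ± 0.33), and the other 14 overlapped, among them POLR1B (-0.44 ± 0.36) and the initiation factor RRN3 (-0.06 ± 0.36). The 2 lower genes compare with a mean of 2.12 apart in random lists. The median of the list, -0.12, lay within the random range of -0.15 to 0.19. It was -0.06 when only genes of at least 5 FPKM were kept. It lay below its random range after removal of the GC and length trend (-0.19), but not when random lists were matched on GC content. Of the 22 RNA polymerase III genes 4 were lower and none was higher. These were BRF1 (-1.40 ± 0.80), POLR3K (-1.03 ± 0.33), POLR3H (-0.79 ± 0.51) and POLR3B (-0.68 ± 0.41). POLR2A, the largest subunit of RNA polymerase II, was higher at 17.4 against 8.02 FPKM (1.02 ± 0.33), and the other 6 polymerase II subunit genes overlapped.

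The immediate early genes, transcription factors and regulators that respond within minutes to many stimuli, had the highest median of the lists, 0.49, above all 10000 random lists (range -0.11 to 0.13). Of 34 members 17 were higher and 4 lower, 21 apart in all against a mean of 4.82 in random lists. FOS, ATF3 (22.6 against 8.16 FPKM, 1.36 ± 0.33) and CTGF (1.24 ± 0.30) were higher. JUND (-1.34 ± 0.33) and MYC were lower. Interferon-stimulated genes had a median of 0.15 (random range -0.16 to 0.13), with 6 of 26 higher and none lower. The 6 compare with a mean of 4.57 apart in random lists. The higher ones included IFI27 (0.69 ± 0.43), IFI6 (0.68 ± 0.34), IFIT1 (0.63 ± 0.29) and OASL (0.56 ± 0.29). This list lay within the random range when the filter was dropped (median 0.04) or raised to 5 FPKM (0.13). NF-kB target and chemokine genes had 4 of 18 higher, among them IL8, the deubiquitinase CYLD (0.97 ± 0.28) and NFKB2 (0.56 ± 0.34). Only 1 was lower, BIRC3 (-0.76 ± 0.26). The 5 apart compare with a mean of 2.98 in random lists. The median of the NF-kB list lay within the random range (0.09), but above it after removal of the GC and length trend (0.18). It was 0.03 without a filter and 0.04 with ribosomal protein scaling.

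Genes known as p53 targets included 6 of 32 that were higher and 2 that were lower, 8 apart against a mean of 4.46 in random lists. The median of the p53 targets, 0.13, lay at the 96.8th percentile of the random lists, just within the range (-0.11 to 0.13). It left the range when only genes of at least 5 FPKM were kept (0.15), when quantile normalization was used instead (0.14), or when the random lists were also matched on GC content. It stayed within the range under the other settings, for example with ribosomal protein scaling (0.08) or the GC and length trend removed (0.10). Besides CDKN1A, the higher ones included PMAIP1, the pro-apoptotic NOXA (113.0 against 54.7 FPKM, 1.03 ± 0.36), SESN2 (0.99 ± 0.31) and TP53INP1 (0.69 ± 0.29). ATF4 and integrated stress response genes went both ways. Of 32 members 5 were higher and 7 lower, 12 apart against a mean of 4.22 in random lists, and the median of -0.08 was within the random range. The median lay below its range without a filter (-0.06) and with quantile normalization (-0.12). ATF4, the transcription factor of this response, was lower at 92.1 against 228.1 FPKM (-1.30 ± 0.38), as was its target CHAC1 (-1.53 ± 0.30). PPP1R15A, the stress-induced phosphatase subunit GADD34 (1.42 ± 0.34), and ATF3 were higher. None of 23 endoplasmic reticulum chaperone genes had intervals apart, and their median of 0.03 and mean of -0.0058 differed in sign (median -0.02 with ribosomal protein scaling). SDF2L1 (-0.48 ± 0.34) and HERPUD1 (-0.43 ± 0.32) were nearest to separation. Among 16 heat shock genes HSPA8 (-0.76 ± 0.45) and DNAJB1 (45.03 against 91.1 FPKM) were lower and DNAJB4 (0.77 ± 0.31) was higher, with a median of -0.05.

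Genes of G1/S and DNA replication had a median of -0.17, below the random range of -0.06 to 0.12, with 39 of 50 ratios below 0, 5 lower with intervals apart and none higher. The 5 compare with a mean of 6.07 apart in random lists. The replication licensing factor CDT1 (-1.07 ± 0.34), the chromatin assembly genes CHAF1A (-0.85 ± 0.34) and CHAF1B (-0.52 ± 0.33), and SLBP, which binds the stem-loop of histone mRNA (-0.68 ± 0.36), were among the lower ones. G2/M genes had a median of -0.0010 (0.0050 with median scaling, -0.05 with ribosomal protein scaling and -0.04 with the GC and length trend removed), and only the mitotic kinase AURKB was lower (-0.60 ± 0.34), 1 apart against a mean of 5.74 in random lists (central 95% from 2 to 10). Replication-dependent histone genes had a median of -0.20 (random range -0.01 to 0.12), with 11 of 48 lower and 6 higher, 17 apart against a mean of 4.61 in random lists. HIST1H1E stood at 447 against 1551 FPKM and HIST3H2BB at 162 against 410 FPKM (-1.33 ± 0.36). The higher members HIST1H2BG (1.31 ± 0.52) and HIST1H2AE (1.05 ± 0.49) were at 0.63 FPKM in control. Histone genes are near-identical copies, so reads may have been divided among them. In the DNA damage response and repair list 5 of 49 were lower and 3 higher, 8 apart against a mean of 7.55 in random lists. The median lay within the random range (-0.07). This median lay below its range after removal of the GC and length trend (-0.11) and when random lists were matched on GC content. The histone variant gene H2AFX had the largest change, at 75.01 against 239.5 FPKM (-1.66 ± 0.36), followed by XRCC3 (-1.08 ± 0.64), XRCC2 (-0.70 ± 0.31) and NBN (-0.66 ± 0.35).

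SR protein and splicing regulator genes had 7 of 36 lower and 2 higher, 9 apart against a mean of 3.95 in random lists. Their median lay within the random range (-0.01), but below it after removal of the GC and length trend (-0.10). The 4 largest changes were all lower SR protein genes, SRSF3 (93.4 against 182.4 FPKM, -0.96 ± 0.39), SRSF2 (-0.89 ± 0.44), SRSF6 (-0.73 ± 0.39) and SRSF4 (-0.73 ± 0.33). The hnRNP genes had a median of -0.08, below the random range (-0.06 to 0.16), with HNRPDL (-0.80 ± 0.37) and HNRNPR (-0.63 ± 0.37) lower and none higher. Ratios were below 0 for 13 of the 22 genes and above 0 for 9. The 2 apart compare with a mean of 1.96 in random lists. Of 331 numbered zinc finger genes 37 were higher and 37 lower, with a median of 0.01 (-0.03 with ribosomal protein scaling and -0.00098 without small RNA genes). When only genes of at least 5 FPKM were kept, the median was 0.10, above its random range. ZNF697 (-1.16 ± 0.22), ZNF696 (-1.15 ± 0.28) and ZNF32 (-1.02 ± 0.32) were lower, and ZNF75A (1.05 ± 0.31) was higher.

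**Figure D3:**
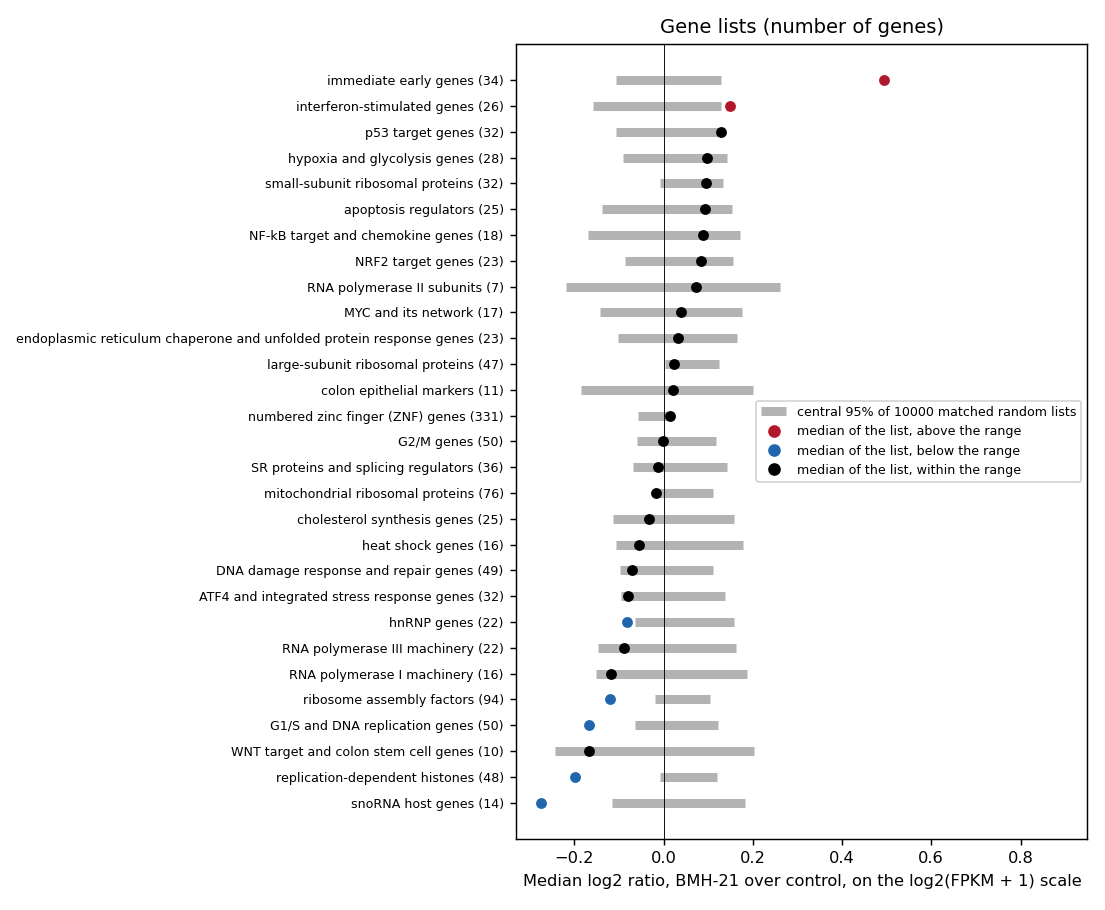
Median log2 ratio (BMH-21 over control, log2(FPKM + 1) scale) of the 29 gene lists, with the number of genes in brackets; grey bars span the central 95% of 10000 random lists matched on mean FPKM. The medians of immediate early (0.49) and interferon-stimulated genes (0.15) lie above their bars, and those of snoRNA host genes (-0.27), histones (-0.20), G1/S and DNA replication genes (-0.17), ribosome assembly factors (-0.12) and hnRNP genes (-0.08) lie below.

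In the remaining lists the medians lay within their random ranges, except that of hypoxia and glycolysis genes after removal of the GC and length trend (0.12). Of 17 genes of MYC and its network 2 were higher, the MYC antagonists MXD1 (1.05 ± 0.21) and MXD4 (0.56 ± 0.29), and 2 were lower, MYC and the spermidine synthase gene SRM (-0.52 ± 0.34); the median of 0.04 and mean of -0.03 differed in sign (median -0.02 with ribosomal protein scaling). The WNT antagonist DKK1 was lower at 224 against 729 FPKM (-1.70 ± 0.41), and MYB was lower (-0.51 ± 0.22), while SOX9 (0.75 ± 0.32) and AXIN2 (0.39 ± 0.25) were higher, 4 apart of 10 in the WNT list. Cholesterol synthesis genes had 2 of 25 lower, MVK (-0.57 ± 0.32) and DHCR7 (-0.56 ± 0.35), against a mean of 3.04 apart in random lists. Hypoxia and glycolysis genes had 3 of 28 higher, including P4HA1 (0.65 ± 0.34) and BNIP3L (0.64 ± 0.33), and 3 lower, including HK2 (-0.78 ± 0.34) and VEGFA (-0.63 ± 0.32). Of 23 NRF2 targets 3 were higher, NFE2L2 itself (0.62 ± 0.36), SLC7A11 (0.55 ± 0.34) and OSGIN1 (0.48 ± 0.33), and HMOX1 was lower (-0.84 ± 0.32). Among 25 apoptosis regulators MCL1 (0.59 ± 0.39) and CASP3 (0.58 ± 0.33) were higher and BOK was lower (-1.24 ± 0.32).

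Of 11 colon epithelial markers KRT18 (457 against 987 FPKM, -1.11 ± 0.42) and KRT19 (-0.67 ± 0.42) were lower and KRT20 (1.33 ± 0.28) was higher, and the median of 0.02 and mean of -0.03 differed in sign. This median was -0.12 when only genes of at least 5 FPKM were kept, -0.0011 without a filter and -0.03 with ribosomal protein scaling. Markers of other cell types were near absent in both groups. The median of 12 fibroblast markers was 0.02 FPKM in control and 0.01 FPKM in BMH-21, and only TAGLN and FBLN1 reached a mean of 1 FPKM, of which TAGLN was lower in BMH-21 (-1.07 ± 0.34). The median of 12 leukocyte markers was 0.05 FPKM in both, and only CD68 reached 1 FPKM (2.43 in control and 2.22 in BMH-21). No mitochondrially encoded gene is among the symbols of the table.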

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

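Half-widths 1.5 times as wide and the root of the summed squared half-widths as a limit were chosen after seeing the data. So were the GC and length correction and the matching on GC content. The other settings were planned, although the interval calls and random lists to which they were applied were not. What most decided the number of genes was how the deposited bounds are read. Intervals 1.5 times as wide left 780 genes apart (288 higher, 492 lower), and a difference larger than the root of the summed squared half-widths gave 3336 (1488 higher, 1848 lower), against 1958 as reported. A filter at 5 FPKM gave 1212 (535 higher, 677 lower), by testing fewer genes. The number of genes changed at least 2-fold was 474 with a pseudocount of 0.1 and 126 with one of 5, against 292, since a larger pseudocount shrinks the ratio. The number of lists outside the random range was 7 as reported, 7 to 9 under the planned settings, 10 with matching on GC content and 14 after removal of the GC and length trend. That removal put RNA polymerase I machinery (-0.19), RNA polymerase III machinery (-0.16), DNA damage response (-0.11), SR protein (-0.10) and mitochondrial ribosomal protein genes (-0.06) below the range, and NF-kB target (0.18) and hypoxia genes (0.12) above it. Matching on GC content put p53 target genes above the range and mitochondrial ribosomal protein and DNA damage response genes below it, and left both polymerase lists, SR protein, NF-kB target and hypoxia genes within it. Of the 7 lists, interferon-stimulated genes fell within the range without a filter and at 5 FPKM, and the other 6 stayed outside in the same direction under each setting that was run for lists. No named gene with intervals apart and no list outside the range changed sign under any setting run. The size of the ratio did depend on the pseudocount, most for genes of low FPKM: 12 named genes moved by more than their half-width with 0.1 and 25 with 5. With 0.1 and 5, the log2 ratio was -2.31 and -0.65 for CHAC1 (-1.53 as reported), 1.78 and 0.39 for MXD1 (1.05), -1.93 and -0.44 for ZNF697 (-1.16), and 2.10 and 0.51 for HIST1H2BG (1.31). The share of higher genes among those apart was 42.0% as reported, 33.2% when the 2 groups were scaled on ribosomal protein genes and 45.7% with quantile normalization; each scaling left the median of all genes within 0.04 of 0. No paired analysis was possible because the table holds 1 estimate per group. For the same reason the fits with and without a variance trend, leaving out single replicates, camera with a preset or an estimated correlation, fry and other splits of the samples were not run. Depth is unknown, so the precision of each value is known only through the deposited bounds.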

Other observations

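The tests on the column structure and on the frequency of short RNA genes at 0 were chosen after the result was seen, as were the gene families named in the next paragraph; the other tests were set before their results were seen.

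These families were not set against random lists, so only values and counts are given. A run of neighbouring olfactory receptor genes beside the beta-globin genes on chromosome 11 was expressed in these cells, and 5 of its 8 OR51 members of at least 1 FPKM were higher in BMH-21 and none was lower. OR51B4 stood at 34.3 against 12.5 FPKM (log2 ratio 1.38 ± 0.34), OR51B2 at 14.7 against 6.84 FPKM (1.00 ± 0.34), OR51B6 at 0.97 ± 0.37, OR51Q1 at 0.89 ± 0.35 and OR51M1 at 0.83 ± 0.36. OR51B5, the most abundant at 88.3 against 75.1 FPKM, had overlapping intervals (0.23 ± 0.37), as did OR51I1, OR51I2 and the neighbouring OR52D1. OR52D1 was the only one of 364 other olfactory receptor genes to reach 1 FPKM. MTRNR2L genes, which are nuclear copies resembling mitochondrial 16S rRNA, were lower in 5 of 6 cases, for example MTRNR2L9 at 88.7 against 213 FPKM (-1.26 ± 0.42); such copies can take reads of the mitochondrial transcript. ID1 (126 against 310 FPKM, -1.29 ± 0.37) and ID3 (-1.03 ± 0.34), inhibitors of basic helix-loop-helix factors, were lower, while ID2 overlapped (0.40 ± 0.35).

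A first hypothesis concerned CYP1A1, the gene with the highest ratio in that ranking without short RNA symbols: aryl hydrocarbon receptor targets may be higher together. Of 6 measured targets other than CYP1A1, 3 were higher with intervals apart (50%, exactly the lowest share that had been set beforehand as favouring the hypothesis), against 6.74% of all genes. These were CYP1B1 (6.54 against 1.88 FPKM, log2 ratio 1.39), the receptor-induced gene TIPARP (90.7 against 45.5 FPKM, 0.98) and NFE2L2 (60.5 against 39.0 FPKM, 0.62), while AHRR (0.03), NQO1 (0.20) and ABCG2 (0.03) overlapped. NFE2L2 was also a named gene of the NRF2 target list, so its value may have been known when these targets were chosen. Without NFE2L2 the share would fall below the mark set beforehand. Activation of the receptor by the compound remains a hypothesis, since AHRR and NQO1 did not separate and TIPARP also responds to other stress signals. A second hypothesis, from TMED7-TICAM2, was that read-through transcripts are more abundant. The 31 loci with joined symbols had a median log2 ratio of -0.02 and a mean of 0.06. The median lay at the 44.9th percentile of matched random lists, within their range of -0.15 to 0.11. Ratios were below 0 for 16 loci and above 0 for 15, and 3 loci were higher with intervals apart and none lower. As for TMED7-TICAM2, values of such loci can depend on how reads were assigned. The median therefore does not decide whether read-through transcripts are more abundant.

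The first pattern weighed is that the 3 columns of a group keep 1 order in nearly every gene. Libraries of different depth would break the order by sampling noise in weakly expressed genes, yet it held in at least 99.9% of genes between 0 and 1 FPKM. The midpoint relation held in at least 99.9% of genes with a lower value above 0, as an estimate with 2 bounds requires. A replicate test on these columns would therefore measure the width of the bounds, not the spread between cultures. No biological explanation was tested for this pattern.

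The second pattern is the fall of the log2 ratio with transcript GC content. Across 5 equal bins of GC content, from the lowest to the highest, the median log2 ratio went from 0.12 to -0.12, the share of higher genes from 11.2% to 3.26% and the share of lower genes from 3.71% to 17.3%. The fitted mean trend with GC and length accounts for few of the calls. After its removal, 83.8% of the 1767 genes apart that had a matched transcript stayed apart in the same direction. The median of the lower genes was -0.62 before and -0.60 after. Because the trend is small beside the called ratios, most calls had to stay apart. GC bias that differs from gene to gene is therefore not excluded. For the trend itself, GC bias between the libraries is a candidate explanation. Within 155 cytosolic and mitochondrial ribosomal protein genes, fitted together, the slope was -0.0909 per 10 points of GC. Its 95% bootstrap interval, -0.14 to -0.04, includes the -0.11 of all genes. Among genes of at least 5 FPKM the slope was negative in each of 5 bins of expression. It was -0.06 in the highest bin and between -0.13 and -0.12 in the others, so it was not alike for all transcripts. The bootstrap interval includes that -0.06 as well. An action of BMH-21 on GC-rich genes would give the same trend, and with 1 estimate per group it stays open and untested.

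The third pattern is the short RNA genes listed at 0 in 1 group only, 58 of 299 (19.4%), against 1 of 11894 other genes (MIRLET7E, itself a short RNA). They were at 0 in control in 35 cases and in BMH-21 in 23, so 60.3% shared a direction. This was under the 65% set beforehand as speaking against a change of these RNAs in 1 direction. If the zeros are failed estimates, however, their split cannot decide whether these RNAs changed. Unstable estimates of genes shorter than a sequenced fragment may account for the pattern. In control, 36 of 147 short RNA genes with a lower bound above 0 had half-widths under 10% of the estimate, against 7 of 11701 other genes. Narrow bounds do not by themselves show that an estimate is unstable, so this comparison does not decide the cause.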
